A study of Mus musculus with 4 samples.

How the data were processed

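The series holds 4 droplet single-cell libraries (10x Genomics, sequenced on an Illumina NextSeq 500, per the labels) of the mouse pancreatic cancer line PiKP-785, 1 per condition: on (0 days without doxycycline, 1 µg/mL), 3 days off, 5 days off and on-off-on, for which the labels give no dose or times. Deposited per library were a matrix of UMI counts per gene and barcode, the gene table (Ensembl identifier and symbol of 27998 genes, the same in all libraries) and the barcode list. The counts are whole numbers with no normalization, as the values show. Cell Ranger 2.1.0 and genome build mm10 are named in the submitters' processing notes. The annotation release, the aligner settings and the rule for calling cells are not given in the sources used here.

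The files held 685, 787, 891 and 769 barcodes for on, 3d off, 5d off and on-off-on. A barcode was kept with at least 1000 detected genes and at most 20% of its UMIs from mitochondrially encoded genes, which removed 1, 9, 13 and 12 barcodes. Doublets were scored per library with Scrublet at an expected rate of 5% (6, 8, 9 and 0 called) and kept in the main sums. UMIs of the kept cells were summed per library, because cells are not replicates, and scaled to the library's total (CPM). The 20 most abundant genes took 20.4%, 18.5%, 17.3% and 19.4% of the totals and mitochondrially encoded genes 4.02%, 5.51%, 5.37% and 4.91%. The floor of 3 counts is 0.080, 0.095, 0.084 and 0.093 CPM. For single levels the 95% interval is the exact Poisson one.

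5 comparisons were made: 3d off against on, 5d off against on, 5d off against 3d off, on-off-on against on, and on-off-on against 5d off. The comparisons that use the same library share its counting error and any error in its preparation, so agreement between them is not independent. With 1 library per condition no test was possible. Each of the 7032 genes with a mean over the 4 libraries of at least 10 CPM has a log2 ratio of CPM after 0.5 counts were added to each sum, with an exact binomial interval conditional on the summed count, and genes were counted by size at 2-fold. Against a library with no UMI the fold is a lower bound computed from the floor. All genes together were shifted by more than 0.1 log2 units in every comparison, so medians of gene lists are reported relative to the median of all compared genes. The raw form planned at first is given where its sign differs. Counts by size with median-of-ratios scaling stand beside the main ones.

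35 pathway lists and 10 lists of cell type markers were fixed before the data were examined, as were the comparisons, filters, rule for named genes and most alternatives. Ca9 and Trac were not among the symbols. The pathway lists cover ERK output, immediate early genes, S and G2/M phase, kinase inhibitors and quiescence, RAS core, receptor kinases, MYC, YAP/TAZ, TGF-beta, WNT and NRF2 targets, p53 targets, apoptosis, stem markers and chromatin regulators. They also cover glycolysis, hexosamine and pentose phosphate, respiratory chain, mitochondrially encoded, lysosome, cholesterol, fatty acid synthesis and oxidation, ribosomal protein, stress response, heat shock, hypoxia, interferon, MHC class I, cytokine, epithelial, mesenchymal, collagen and housekeeping genes. Some genes stand in more than 1 list, such as Slc7a11, Serpine1 and Tgfb2. Each list's median was placed among 10000 random lists of the same size drawn from 20 bins of mean CPM, as a description of these libraries. Named genes are Kras, the 12 highest and 12 lowest of each comparison without mitochondrially encoded, ribosomal protein, predicted and clone genes, and up to 4 members per list with the largest ratio. A few list members and markers outside that rule are named by their list alone. Coordinates come from GENCODE M21 (GRCm38, the same assembly as mm10), matched on Ensembl identifier for 7026 of the 7032 genes.

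For measures per cell, every cell was thinned at random to 16627 UMIs, the lowest of the libraries' 10th percentiles; 8, 31, 50 and 76 shallower cells were left out. Phases were called with scanpy from the S and G2/M lists. ERK output per cell was compared with the 5th percentile of on cells, and shares of cells have Clopper-Pearson intervals. Clusters used 2000 variable genes without S, G2/M, mitochondrially encoded and ribosomal protein genes, 30 principal components, 15 neighbours and Leiden resolution 0.5, with no batch correction.

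The steps were tested on simulated Poisson counts for 3d off against on, with no spread between cells or libraries. This checks the computation only, since at this depth counting error alone takes hardly any gene past 2-fold. Ratios were taken against the simulated totals, which the changed genes also move. Of 6832 unchanged genes 0% passed 2-fold, and 94.9% of intervals held the true ratio. For 50 genes each made 2-fold and 4-fold higher, the median log2 ratios were 0.92 and 1.93. For 50 genes each made 0.5-fold and 0.25-fold, they were -1.07 and -2.07. Alternatives tried were median-of-ratios scaling, totals without mitochondrially encoded and ribosomal protein genes, equal weight per cell, no and stricter cell filters, doublets removed, G1 cells alone, other low-count minimums and fold sizes, and other bins. For cells and return they were other thinning, clustering settings and gene selections. Added after the data were seen were leaving out the cells of cluster 5 and the barcodes under 1% mitochondrial UMIs. Versions were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.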

Results

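PiKP-785 is a primary mouse pancreatic ductal adenocarcinoma line in which oncogenic Kras is switched on by doxycycline. Droplet single-cell RNA sequencing was run on cells kept in 1 µg/mL doxycycline (on), on cells 3 or 5 days after its withdrawal (3d off, 5d off), and on cells in which doxycycline was taken away and given back (on-off-on; the labels give neither the times nor the dose of this return). There was 1 library per condition, so no difference has a replicate check, and every interval covers counting error only. After filtering, the on, 3d off, 5d off and on-off-on libraries held 684, 778, 878 and 757 cells with 37391856, 31566790, 35721880 and 32299027 UMIs. The median cell had 49928, 37410, 34536 and 38140 UMIs in the same order. Genes whose symbol starts with Rpl or Rps and a digit took 43.1%, 34.8%, 26.1% and 34.6% of UMIs. The makeup of the library totals thus differed between conditions. Ribosomal protein genes left out of totals, clustering and named genes were taken by this symbol pattern, which is not exactly that class. Where a pair of levels is given, that of the reference library of the comparison comes first. Levels are the UMIs of the summed cells scaled to the library total (CPM), and 7032 genes with a mean of at least 10 CPM were compared. For lists of genes the median log2 ratio is given relative to the median of all compared genes, with members called higher or lower at 2-fold by total UMIs. The counts of members thus keep the shift of all genes, which the medians do not. A list is reported for a comparison when its median lay at or outside the 2.5th and 97.5th percentiles of 10000 random lists matched on size and expression. Under the alternatives the random lists were not redrawn, and medians are set against the span of the main analysis.

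Kras checks the labels. Its level (chromosome 6, 145216699 to 145250239, ENSMUSG00000030265) was 318 CPM in the on library (95% Poisson interval 312 to 324), 78.5 CPM (75.4 to 81.7) at 3d off and 120 CPM (116 to 123) at 5d off. It stood at 400 CPM (393 to 407) in on-off-on. The level was thus 4.05-fold lower at 3d off and 2.65-fold lower at 5d off than in the on library. Counts at Kras cannot separate the transgene from the endogenous gene. The on-off-on level was 1.26-fold above that of the on library by total UMIs, a log2 ratio of 0.33 that became -0.02 with median-of-ratios scaling, 0.14 with totals without mitochondrially encoded and ribosomal protein genes, and 0.60 among cells called G1 alone. After every cell was thinned to 16627 UMIs, the median cell held 4 Kras UMIs in the on library, 1 at 3d off, 2 at 5d off and 5 in on-off-on. Of the thinned cells, 81 were called G1 in on-off-on, against 462, 651 and 608 in the on, 3d off and 5d off libraries. G1 values of on-off-on, here and below, thus rest on few cells.

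Genes under ERK control went with Kras in part. Dusp6, the ERK phosphatase that feeds back on the pathway, had 60.8, 20.2, 22.9 and 71.6 CPM in the on, 3d off, 5d off and on-off-on libraries. The ETS transcription factor Etv4 had 15.1, 1.90, 2.44 and 31.6 CPM, and the AP-1 member Fosl1 17.8, 2.47, 4.84 and 63.1 CPM. Other members of the ERK output list did not follow Kras: the ephrin receptor Epha4 had 62.6, 164, 293 and 108 CPM, and the TWEAK receptor Tnfrsf12a 346, 295, 646 and 413 CPM. Summed over the list, the level was 1656 CPM (1643 to 1669) in the on library and 1210 CPM (1198 to 1222) at 3d off. The sum at 5d off, 1998 CPM (1983 to 2012), was above that of the on library by total UMIs but below it with median-of-ratios scaling (1739 against 2039). In on-off-on the sum was 2305 CPM (2288 to 2322). Per thinned cell the list gave a median of 15.6 UMIs per 10000 in the on library, 10.8 at 3d off, 18 at 5d off and 22.9 in on-off-on. Of the 3d off cells, 87.4% (Clopper-Pearson 84.8 to 89.7) lay at or above the 5th percentile of the on cells, against 95.7% (94.0 to 96.9) at 5d off. The on cells themselves gave 95.9%, which the bound fixes by construction. In such a sum abundant members weigh most, and the limit of scaling by total UMIs holds per cell too. The list median at 5d off against on, in which members count alike, was -1.02 relative to all genes.

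**Figure D1:**
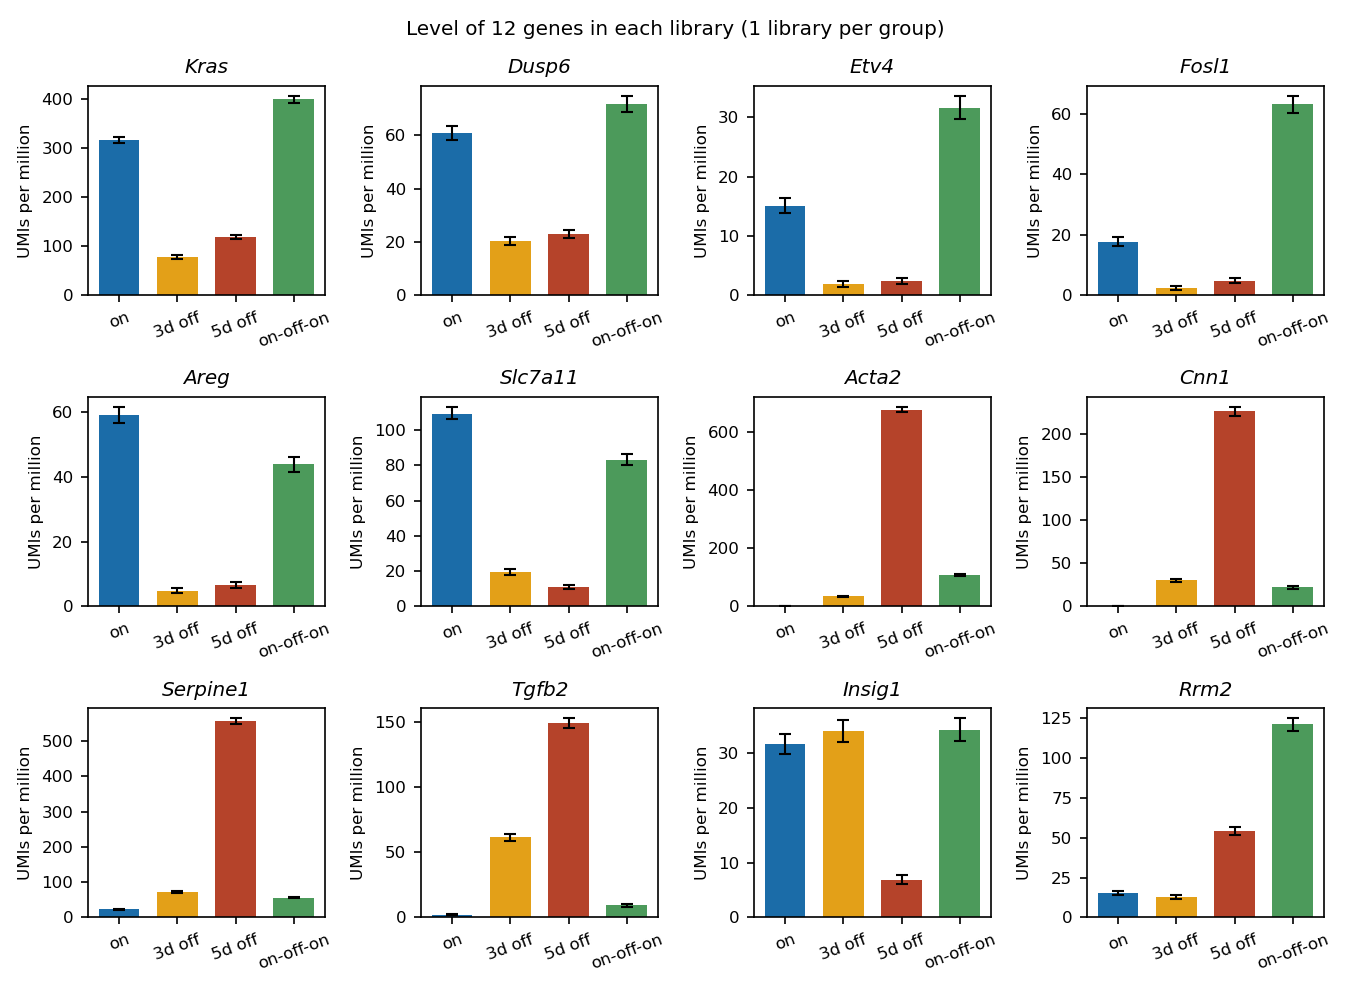
Level in CPM of 12 genes in the on, 3d off, 5d off and on-off-on libraries; each bar is 1 library and each error bar its 95% Poisson interval, which covers counting error only. Kras is at 318, 78.5, 120 and 400 CPM, and Acta2 at 0, 35.4, 677 and 109 CPM.

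The comparison of 3d off with on asks what differs early after the oncogene is turned down. The ERK output, MYC target and G2/M lists had medians below those of their random lists, and the mesenchymal, TGF-beta target and lysosome lists had medians above. Areg, a ligand of the EGF receptor, was 12.2-fold lower (59.0 and 4.82 CPM), and the interleukin-1 receptor antagonist Il1rn 14.3-fold lower (125 and 8.68 CPM). Tgfb2, the TGF-beta 2 ligand, was 30.5-fold higher (2.01 and 61.6 CPM). In all, 793 genes were 2-fold or more higher and 142 lower. The median of all genes was shifted by 0.33 log2 units, and with median-of-ratios scaling the split was 380 higher and 345 lower. At a minimum of 50 CPM the counts were 215 and 44, and with no low-count filter 3055 and 688.

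Among the genes furthest below the on library were the tetraspanin Cd53 (85.4-fold), the mannose receptor Mrc1 (17.3-fold), the proteoglycan aggrecan Acan (12.8-fold), the kinase Prkg2 (7.63-fold) and Etv4 (7.90-fold; log2 ratio -2.98, -3.40 to -2.61). Gcnt3, a mucin glycosyltransferase, and the keratin Krt23 were 7.01-fold and 6.03-fold lower. Hmga1 and its near-identical copy Hmga1-rs1 were 6.25-fold and 6.39-fold lower, but reads can be shared between them, so both values are uncertain. At the other end, the smooth muscle actin Acta2 had no UMI in the on library and 35.4 CPM at 3d off, at least 441-fold higher against a floor of 3 counts. Calponin (Cnn1), with 0.0802 CPM in the on library, had a log2 ratio of 8.34 (7.01 to 10.84), and transgelin (Tagln) one of 7.25 (5.71 to 10.62). The myosin light chain Myl9 was 124-fold higher, the matrix proteins Tnc, Spon2 and Cthrc1 were 49.7-fold, 75.9-fold and 79.2-fold higher, and Acta1 was 82.8-fold higher.

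Of 17 measured ERK output genes, 9 were lower, 1 (Epha4) was higher and 7 lay between, with a list median of -1.33. MYC targets and ribosome biogenesis genes had a median of -0.95, with 4 of 27 lower and none higher; Odc1, the first enzyme of polyamine synthesis, had 707 and 283 CPM. G2/M phase genes had a median of -0.99, with 5 of 41 lower and none higher, among them Ube2c (194 and 77.0 CPM) and Top2a (93.6 and 42.0 CPM), and was at -0.43 among cells called G1 alone. The S phase list was at -0.29 (0.05 before the shift of all genes is taken off), with 1 of 25 members higher and 1 lower, and turned to 0.08 in G1 cells, or to -0.56 at a minimum of 50 CPM. Genes of the integrated stress and unfolded protein responses had a median of -0.76, with 4 of 22 lower; the cystine transporter Slc7a11 was 5.58-fold lower (109 and 19.6 CPM) and the serine synthesis enzyme Psat1 had 156 and 64.6 CPM. Lower medians were also seen for the hexosamine and pentose phosphate pathway (-0.77, or -0.50 at a minimum of 50 CPM, 1 of 12 lower, G6pdx), hypoxia (-0.69, 1 of 10 lower, Ero1l), cytosolic ribosomal proteins (-0.64, none of 33 past 2-fold) and glycolysis (-0.43, none of 16 past 2-fold). Cytokines and chemokines had a median of -0.59 with 3 of 11 higher and 3 lower, and at a minimum of 50 CPM the median turned to 0.40.

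The mesenchymal list had a median of 1.41 at 3d off, with 8 of 14 members higher and none lower. It was 0.93 at a minimum of 5 CPM and 0.54 with no low-count filter. Sparc, a matrix protein, had 14.5 and 101 CPM and the protease inhibitor Serpine1 22.8 and 73.4 CPM. TGF-beta targets were at 0.68 (9 of 14 higher, none lower; Pmepa1 87.4 and 308 CPM) and YAP/TAZ targets at 0.62 (11 of 22 higher, 1 lower; Ctgf 42.2 and 249 CPM, Ankrd1 169 and 641 CPM). Receptor tyrosine kinases and their ligands were at 0.59 (0.14 at a minimum of 50 CPM), with 6 of 13 higher, including Igf1r (60.1 and 167 CPM) and Pdgfb (13.7 and 50.1 CPM). Lysosome and autophagy genes were at 0.51, with 12 of 30 higher and none lower, for example Hexa (25.8 and 68.9 CPM) and the cathepsin Ctsa (36.6 and 109 CPM). Immediate early genes were at 0.51 (1.01 at a minimum of 50 CPM) with 6 of 14 higher. Jun had 13.9 and 72.5 CPM while Egr1 had 90.1 and 75.8 CPM. Fatty acid oxidation (0.42, 2 of 13 higher, with Cpt1a 8.91 and 27.7 CPM), MHC class I presentation (0.35, 3 of 10 higher, with B2m 106 and 252 CPM), housekeeping genes (0.22, 3 of 14 higher, with Actb 1422 and 3230 CPM) and nuclear genes of the respiratory chain (0.10, or 0.03 with each cell weighted alike, 1 of 36 higher, Ndufa9) also lay above their random lists, though housekeeping genes fell within theirs when 10 expression bins were used in place of 20. Medians inside the random span were those of the S phase (0.08), respiratory chain (0.07) and housekeeping (0.16) lists in G1 cells, and of receptor kinases (0.14) and glycolysis (-0.31) at 50 CPM. So were those of the respiratory chain (0.03), MHC class I (0.32) and housekeeping (0.16) lists with each cell weighted alike, and of MHC class I (0.26) with no low-count filter.

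The comparison of 5d off with on asks the same at the later time. The mesenchymal, TGF-beta target and S phase lists had medians above those of their random lists, and the cholesterol synthesis list one below. Acta2 was at 677 CPM, at least 8440-fold above the on library, and Serpine1 at 557 CPM, 24.4-fold higher. Acta2 was uneven over the clusters of 5d off cells given at the end: it was at 262 CPM in cluster 3, with 70.7% of cells, while clusters 6 and 7 (1098 and 5859 CPM) held 49.6% and 26.2% of its UMIs. Slc7a11 was 10.0-fold lower at 10.9 CPM and Insig1, a sterol-regulated gene, had 31.5 and 6.89 CPM. Counted by size, 1625 genes were higher and 253 lower; the median of all genes was shifted by 0.50, and median-of-ratios scaling gave 645 higher and 725 lower. Totals without mitochondrially encoded and ribosomal protein genes gave 816 and 552, a minimum of 50 CPM 515 and 74, and no low-count filter 4399 and 1088.

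Highest beside Acta2 were Cnn1 (log2 ratio 11.24, 9.91 to 13.74), Tagln (10.00, 8.47 to 13.37), Myl9 (442-fold), Acta1 (186-fold), Cthrc1 (166-fold) and the xylosyltransferase Gxylt2 (337-fold). Fhl1, a LIM protein of muscle, and the urotensin peptide gene Uts2b had no UMI in the on library and were at least 457-fold and 573-fold higher. Lowest were Cd53 (log2 ratio -8.92, -12.29 to -7.38), Mrc1 (155-fold), Acan (34.7-fold), the intestinal cadherin Cdh17 (25.4-fold), S100a14 (25.2-fold) and Fgfbp1 (12.1-fold).

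The mesenchymal median was 2.02 (3.21 at a minimum of 50 CPM), with 11 of 14 members higher and none lower, and TGF-beta targets were at 0.86 with 10 of 14 higher (Tgfbr1 6.34 and 33.7 CPM). YAP/TAZ targets stood at 0.83 (13 of 22 higher, none lower; Ankrd1 at 1263 CPM) and lysosome and autophagy genes at 0.69 (19 of 30 higher, none lower; Ctsd 89.1 and 300 CPM). S phase genes were at 0.46, with 12 of 25 higher and none lower; ribonucleotide reductase Rrm2 had 15.2 and 53.9 CPM. Among cells called G1 alone, a choice that takes out cycling cells, the S phase median was -0.12. The G2/M median was -0.31, or 0.19 before the shift of all genes is taken off, with 4 of 41 higher (Birc5 36.7 and 80.1 CPM) and none lower. It was -0.53 both in G1 cells and with each cell weighted alike. Heat shock genes were at 0.49 (5 of 11 higher, with Hspb1 26.7 and 272 CPM), which turned to -1.03 at a minimum of 50 CPM. Housekeeping genes were at 0.41 (6 of 14 higher, with Ppia 1482 and 3503 CPM), within the random range with 10 bins. With the shift of all genes taken off, 2 heat shock members were 2-fold or more higher and 4 lower. On that scale housekeeping genes had 3 higher and 2 lower, YAP/TAZ targets 9 and 3, and lysosome and autophagy genes 8 and 1.

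ERK output genes had a median of -1.02, with 6 of 17 lower and 3 higher; at a minimum of 50 CPM it was -0.36. Cholesterol synthesis genes were at -1.24, with 6 of 20 lower and none higher, among them Pcsk9 (60.6 and 11.3 CPM) and Mvd (34.2 and 9.01 CPM). Cytosolic ribosomal proteins were at -1.21 (6 of 33 lower; Rpl3 4910 and 2265 CPM), and the integrated stress and unfolded protein responses at -1.11 (6 of 22 lower, 3 higher). In that last list the ATF4 targets Trib3 (77.0 and 16.3 CPM) and Psat1 (156 and 64.8 CPM) were low while the chaperone Hspa5 was high (96.0 and 203 CPM). The hexosamine and pentose phosphate pathway was at -0.77 (1 of 12 higher, 1 lower), hypoxia at -0.76 (3 of 10 lower; -0.09 at a minimum of 50 CPM), glycolysis at -0.67 (1 of 16 higher, Pgam1) and MYC targets at -0.57 (2 of 27 higher, 2 lower). Inside the random span lay the S phase (-0.12) and heat shock (0.35) medians in G1 cells and those of ERK output (-0.36), hypoxia (-0.09), glycolysis (-0.48) and G2/M (-0.22) at 50 CPM. The housekeeping median did so at a minimum of 5 CPM (0.32), with no filter (0.33) and with each cell weighted alike (0.32), as did heat shock (0.39) in the last case.

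**Figure D2:**
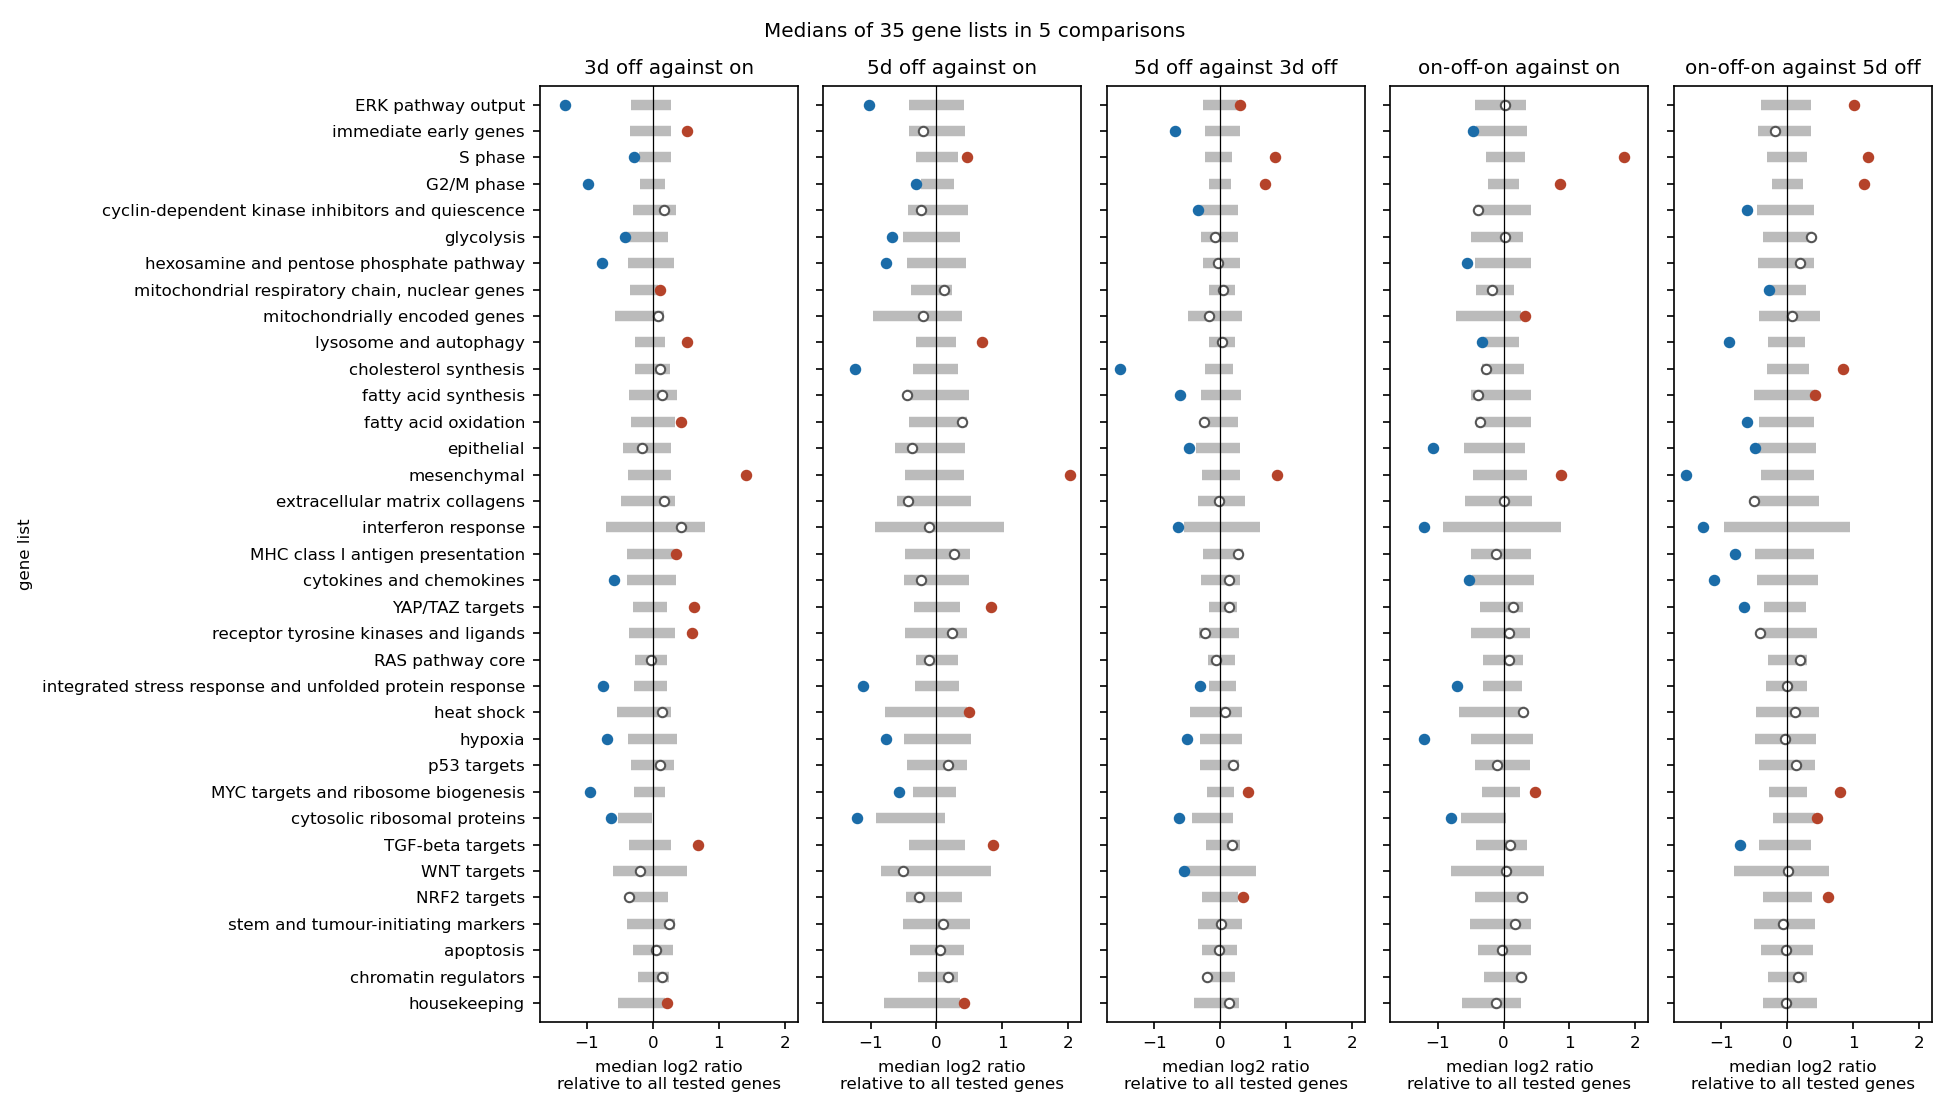
Median log2 ratio of 35 gene lists, relative to all compared genes, in 5 comparisons of 1 library each; a grey bar spans the 2.5th to 97.5th percentile of 10000 matched random lists, a filled red or blue point lies above or below that span and an open point within it. The mesenchymal list lies at 1.41 and 2.02 at 3d and 5d off against on, and the ERK output list at -1.33 and -1.02.

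Set directly against 3d off, the 5d off library had higher medians for the mesenchymal, S phase and G2/M lists, and lower ones for cholesterol synthesis and immediate early genes. TGF-beta targets lay within their random lists (0.18, 1 of 14 higher). Acta2 was 19.1-fold higher, Fhl1 27.9-fold, Gxylt2 7.91-fold, Serpine1 7.59-fold, Cnn1 7.46-fold, the matrix protein Thbs1 5.11-fold and the prostaglandin synthase Ptgs2 5.32-fold higher. Fgfbp1 was 11.2-fold lower, the immediate early factors Egr1 and Fos 9.33-fold and 6.05-fold lower, the galectin Lgals4 6.98-fold and the clock gene Dbp 5.83-fold lower. Here 296 genes were higher and 132 lower, with all genes shifted by 0.17; median-of-ratios scaling gave 183 higher and 195 lower. Totals without mitochondrially encoded and ribosomal protein genes gave 165 and 220, a minimum of 50 CPM 98 and 31, and no low-count filter 1396 and 1001. At 5 CPM 212 were lower.

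Cholesterol synthesis genes had a median of -1.52 in this comparison, with 13 of 20 lower and none higher (Insig1 4.91-fold lower; Fdps 161 and 50.3 CPM). Fatty acid synthesis was at -0.60 (3 of 11 lower; Scd1 113 and 32.6 CPM). Immediate early genes stood at -0.69 (4 of 14 lower), cytosolic ribosomal proteins at -0.62 (none of 33 past 2-fold), hypoxia at -0.50 (1 of 10 higher; 0.38 at a minimum of 50 CPM), epithelial genes at -0.47 (1 of 12 lower, Tff2), quiescence genes and cyclin-dependent kinase inhibitors at -0.34 (2 of 12 lower, Txnip and Cdkn1a) and the stress responses at -0.30 (1 of 22 lower, Trib3). The interferon (-0.63) and WNT (-0.55) lists had only 3 and 5 measured members; Porcn was the WNT member past 2-fold, and that median was -0.02 with no low-count filter. Higher medians were found for the mesenchymal list (0.86, or 1.49 at a minimum of 50 CPM; 7 of 14 higher), S phase (0.83, 13 of 25 higher; Rrm2 12.7 and 53.9 CPM), G2/M phase (0.68, 17 of 41 higher; Birc5 25.9 and 80.1 CPM), MYC targets (0.43, 3 of 27 higher, with Srm 27.2 and 59.5 CPM), NRF2 targets (0.35, none of 16 higher and Gsta4 lower) and ERK output (0.30, 2 of 17 higher, Tnfrsf12a and Plaur). Among cells called G1 alone the S phase, G2/M and MYC target medians were -0.18, -0.05 and 0.25. The 50 CPM minimum gave 0.58 for ERK output, -0.61 for quiescence genes, 0.28 for MYC targets, -0.22 for WNT and 0.17 for NRF2 targets. WNT was at -0.32 with a minimum of 5 CPM, interferon at -0.23 with no low-count filter and epithelial genes at -0.31 with every barcode kept. All of these but the 50 CPM values of ERK output, quiescence and MYC targets, and the G1 value of MYC targets, lay inside the random span. Also inside it were ERK output (0.25 with each cell weighted alike, 0.20 at 5 CPM, 0.26 with no filter), quiescence genes (-0.25 with the stricter cell filter, -0.28 with no filter, -0.23 without barcodes under 1% mitochondrial UMIs), and epithelial genes (-0.35 weighted alike, -0.34 at 50 CPM). The interferon list (-0.42 weighted alike and at 5 CPM, -0.48 in G1 cells) and the WNT list (-0.38 weighted alike, -0.43 in G1 cells) were inside as well.

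On-off-on against on asks how far cells given doxycycline again resembled cells kept in it. Cell cycle genes were above the on library: Rrm2 had 121 against 15.2 CPM, the replication helicase subunit Mcm3 42.9 against 5.86, Birc5 235 against 36.7 and Mki67 61.3 against 19.1 CPM. The transferrin receptor Tfrc was 16.2-fold higher (4.73 and 76.7 CPM). The stress response gene Ddit3 was 7.77-fold lower and Gadd45a 7.08-fold lower. In number, 1079 genes were higher and 269 lower; all genes were shifted by 0.36, and median-of-ratios scaling gave 437 higher and 582 lower. Totals without mitochondrially encoded and ribosomal protein genes gave 650 and 423, a minimum of 50 CPM 275 and 78, and no low-count filter 3203 and 1014.

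Smooth muscle actin was also above the on library, with Acta2 at 109 CPM (at least 1354-fold), as were Cnn1 at 22.1 CPM (log2 ratio 7.89, 6.56 to 10.39), Tagln at 7.68 CPM (6.85, 5.30 to 10.22) and Myl9 at 25.6 CPM (46.8-fold). A large part of this came from few barcodes: without those under 1% mitochondrial UMIs, an alternative chosen after the data were seen, Acta2 was at 24.2, Cnn1 at 8.87, Tagln at 3.18 and Myl9 at 7.82 CPM. Low genes included Dbp (10.9-fold), the ectonucleotidase Entpd2 (8.82-fold), Angptl6 (8.12-fold), S100a14 (8.07-fold), Pdlim4 (7.60-fold), Ypel3 (5.57-fold) and the fructose kinase Khk (5.23-fold). In G1 cells the log2 ratios of Entpd2, Pdlim4 and Ypel3 were smaller, at -1.92, -1.91 and -1.53.

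S phase genes had a median of 1.82 with 22 of 25 higher, and G2/M genes one of 0.86 with 28 of 41 higher, none being lower in either list. Among cells called G1 alone, 81 in on-off-on and 462 in the on library, these medians were 0.33 and 0.26, and the count of higher genes was 597. MYC targets were at 0.47 (12 of 27 higher, with Odc1 at 1248 CPM; Npm1 lower), the mesenchymal list at 0.87 (8 of 14 higher) and mitochondrially encoded genes at 0.32 (3 of 12 higher, with mt-Nd1 2802 and 7919 CPM; within the random range with 10 bins). Hypoxia genes were at -1.21 (4 of 10 lower; -0.34 at a minimum of 50 CPM), epithelial genes at -1.07 (3 of 12 lower; Krt7 601 and 273 CPM), cytosolic ribosomal proteins at -0.79 (none of 33 past 2-fold) and the stress responses at -0.71 (5 of 22 lower, 1 higher). The hexosamine and pentose phosphate pathway (-0.56, 1 of 12 higher, Pgd), immediate early genes (-0.46, 2 of 14 lower, Egr1 and Fos, and Jun higher) and lysosome genes (-0.32, or 0.03 before the shift of all genes is taken off; 1 of 30 lower, Npc2) were also low. So were the 3 measured interferon genes (-1.21, or -0.42 with no low-count filter; Ifi27 16.3 and 5.36 CPM). Cytokines and chemokines were at -0.53 (2 of 11 higher, 1 lower), which turned to 0.05 with no low-count filter. In G1 cells the medians of lysosome genes (-0.03), MYC targets (0.11), immediate early genes (-0.23), epithelial genes (-0.56), the interferon genes (-0.68), cytokines (-0.02), ribosomal proteins (-0.53) and the hexosamine and pentose phosphate pathway (-0.42) lay nearer 0, inside the random span found with all cells, while the mesenchymal median was 1.40. Of 11 thinned on-off-on cells in cluster 3, a cluster given at the end and made mostly of 5d off cells, only 2 were called S or G2/M. Such cells thus weigh more in the G1 values than in those of all cells. With a minimum of 5 CPM, the mesenchymal, interferon and cytokine medians were 0.47, -0.78 and -0.02. The hexosamine and pentose phosphate median was -0.85 at 50 CPM and -0.36 with no filter, and the epithelial one -0.49 with no filter. Other alternatives also put medians inside the random span: at 5 CPM those of interferon, cytokines, hexosamine (-0.39) and lysosome genes (-0.29), and with no filter those of interferon, cytokines, hexosamine, epithelial and lysosome genes (-0.27). The 50 CPM medians of hypoxia, immediate early (-0.36) and mitochondrially encoded genes (0.22) were inside, as was that of lysosome genes (-0.30) without barcodes under 1% mitochondrial UMIs. The ERK output list lay within its random lists (0.02, or 0.25 in G1 cells, percentile 60.0), with Fosl1, Spry2 and Etv4 higher and Dusp4 lower; Spry2 had 47.5 CPM, or 22.9 without a cluster of cells described among the clusters.

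Against 5d off, the on-off-on library had higher medians for the ERK output, MYC target, S phase and G2/M lists, and lower ones for the mesenchymal and lysosome lists. Kras was 3.34-fold higher, Etv4 12.9-fold, Il1rn 11.5-fold, Slc7a11 7.65-fold, Acan 25.8-fold and Cdh17 24.5-fold higher. Mrc1 was 251-fold higher, and Cd53, with 0.0560 CPM at 5d off, had a log2 ratio of 6.85 (5.31 to 10.23). Tgfb2 was 16.2-fold lower, Cthrc1 55.5-fold, Uts2b 21.7-fold, Spon2 18.3-fold, Wisp1 18.1-fold, the metalloproteinase inhibitor Timp3 14.8-fold (644 and 43.5 CPM), Synpo 13.9-fold and the endothelin gene Edn1 12.6-fold lower. By size, 329 genes were higher and 822 lower, with all genes shifted by -0.15; median-of-ratios scaling gave 477 and 610. Totals without mitochondrially encoded and ribosomal protein genes gave 507 higher, a minimum of 50 CPM 76 higher and 285 lower, and no low-count filter 1377 and 2652. The log2 ratio of Tgfb2 was -4.02, or -2.67 in G1 cells.

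High medians were those of S phase (1.22, 13 of 25 higher), G2/M phase (1.16, 21 of 41 higher), ERK output (1.02, 8 of 17 higher, 2 lower; 0.49 at a minimum of 50 CPM), cholesterol synthesis (0.85, 8 of 20 higher; 0.18 at a minimum of 50 CPM), MYC targets (0.81, 8 of 27 higher), NRF2 targets (0.62, 3 of 16 higher, 2 lower), cytosolic ribosomal proteins (0.46, none of 33 past 2-fold) and fatty acid synthesis (0.42, 2 of 11 higher, Elovl6 and Fasn; within the random range with 10 bins). Insig1 had 6.89 and 34.2 CPM (21.6 in on-off-on without cluster 5, an alternative added after the data were seen) and Pcsk9 11.3 and 55.4 CPM. Low medians were those of the mesenchymal list (-1.54, 9 of 14 lower), interferon (-1.27, 3 of 3 lower), cytokines and chemokines (-1.11, 6 of 11 lower, 4 higher), lysosome and autophagy (-0.88, 16 of 30 lower), MHC class I (-0.79, 5 of 10 lower) and TGF-beta targets (-0.72, 6 of 14 lower). YAP/TAZ targets (-0.65, 10 of 22 lower, 1 higher), fatty acid oxidation (-0.61, 5 of 13 lower), kinase inhibitors and quiescence (-0.60, 3 of 12 lower, 1 higher), epithelial genes (-0.49, 3 of 12 lower) and the nuclear respiratory chain genes (-0.27, 3 of 36 lower) followed. With the shift of all genes taken off, epithelial genes had 1 lower and 2 higher, and quiescence genes 2 lower and 2 higher. B2m had 404 and 99.3 CPM, Hexa 78.6 and 14.1 CPM and Serpine1 was 9.88-fold lower. Among cells called G1 alone 174 genes were higher, and the S phase, G2/M, interferon and cytokine medians were 0.56, 0.76, -0.45 and -0.45. Those of the nuclear respiratory chain, MHC class I, lysosome and epithelial lists were -0.05, -0.46, -0.55 and -0.26 in these cells, and that of ribosomal proteins 0.82. Of these, the interferon, cytokine, respiratory chain, MHC class I and epithelial values lay inside the random span found with all cells. The 50 CPM minimum gave -2.47 for mesenchymal genes, -1.47 for YAP/TAZ targets, 0.77 for G2/M and 0.34 for NRF2 targets. With no low-count filter fatty acid synthesis was at 0.26 and MHC class I at -0.44, and with each cell weighted alike quiescence genes were at -0.39. These last values lay inside the random span, as did cholesterol synthesis and NRF2 targets at 50 CPM and epithelial genes at 5 CPM and with no filter (-0.42 in both). So did fatty acid synthesis at 50 CPM (0.31), weighted alike (0.32) and without barcodes under 1% mitochondrial UMIs (0.41), quiescence genes with no filter (-0.42), and the respiratory chain without cluster 5 (-0.23).

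To ask whether the early differences ran the other way after doxycycline was given back, genes were selected on 3d off against on and read out on on-off-on against 5d off, so that no library served both steps. Of the 793 genes higher at 3d off, 457 were 2-fold or more lower on return (57.6%, Clopper-Pearson 54.1 to 61.1), against 11.7% of all genes. Of the 142 lower genes, 89 were 2-fold or more higher on return (62.7%, 54.2 to 70.6), against 4.68% of all genes. In on-off-on against on, the median log2 ratios of these sets were 0.58 and -0.24 before any shift is taken off. All genes were shifted by 0.36 there, so relative to them the higher genes lay nearer the on level and the lower genes further below it. That comparison also shares the on library with the selection. With selection on 5d off and readout against 3d off instead, the shares were 19.6% and 25.3%. No share over all genes stands beside these values, so the drop cannot be read as a weaker return. Within the random range in all 5 comparisons were the lists of extracellular matrix collagens, RAS pathway core, p53 targets, stem and tumour-initiating markers, apoptosis and chromatin regulators. Single members still differed: the chromatin protein Hmga2 had 392, 93.0, 83.8 and 516 CPM and the cell death gene Bmf 3.72, 39.2, 22.2 and 2.04 CPM in the on, 3d off, 5d off and on-off-on libraries.

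Phase calls from the S and G2/M lists in thinned cells alone show no cycling. Pooled levels of the G2/M genes Mki67 and Top2a are given beside them. The calls put 31.7% (28.2 to 35.3) of on cells, 12.9% (10.5 to 15.5) of 3d off cells, 26.6% (23.6 to 29.7) of 5d off cells and 88.1% (85.4 to 90.4) of on-off-on cells in S or G2/M. S phase took 4.88%, 3.08%, 12% and 34.9% of cells. Pooled levels in the same order were 19.1, 10.1, 21.8 and 61.3 CPM for Mki67 and 93.6, 42.0, 74.8 and 225 CPM for Top2a. A Mki67 UMI was seen in 16.0%, 6.56%, 14.3% and 54.9% of thinned cells. For Acta2 the shares were 0 of 676 on cells, which allows up to 0.544% of thinned cells with a UMI and sets no limit on cells that express the gene, then 5.22%, 39.1% and 8.52%, and for Cnn1 0 of 676, 15.7%, 49.2% and 6.02%. All cells are of 1 line, so no cell type that lacks these genes could measure free RNA, and its part in these shares and calls is open.

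**Figure D3:**
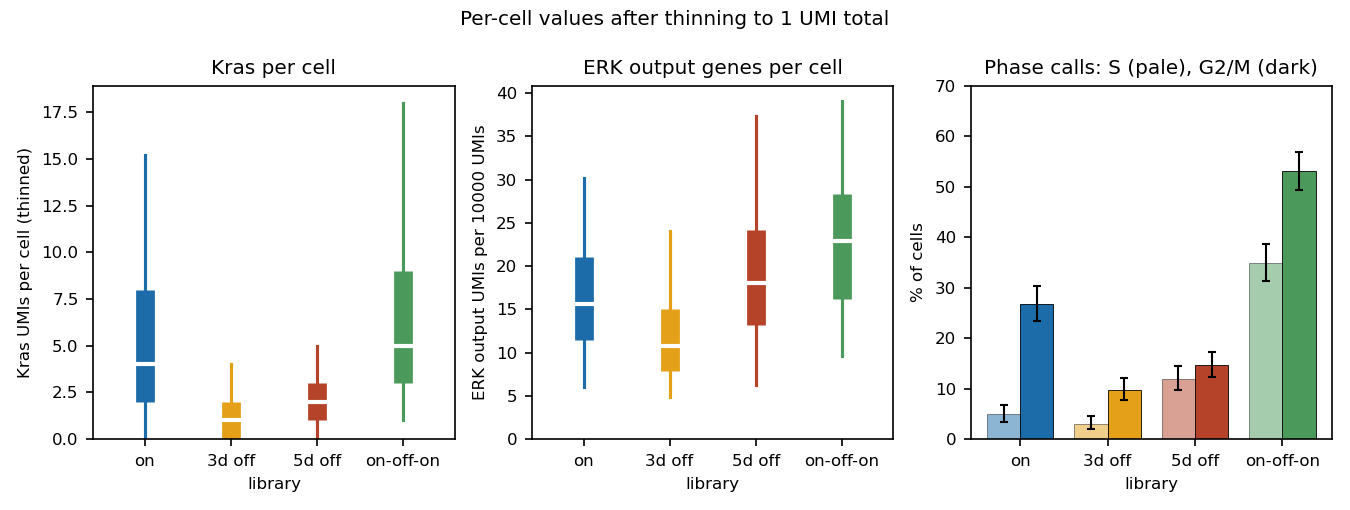
Per-cell measures in the 4 libraries after thinning to 16627 UMIs: Kras UMIs per cell and ERK output UMIs per 10000 (5th, 25th, 50th, 75th and 95th percentiles over cells), and the % of cells called S (pale) or G2/M (dark) with Clopper-Pearson 95% intervals. The on-off-on library has 34.9% of cells in S and 53.2% in G2/M, against 3.08% and 9.77% at 3d off.

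Clustering all 3097 cells gave 7 clusters, most of them made of 1 library. Clusters 1, 2, 3 and 4 held 86.5% of 3d off cells, 97.4% of on cells, 70.7% of 5d off cells and 62.7% of on-off-on cells. Library and condition are the same here, so such a cluster can be either. The 5d off library held a further group, cluster 6, with 18.8% of its cells, and the on-off-on library cluster 5, with 31.8%. Cluster 7 held 4.56% of 5d off and 2.38% of on-off-on barcodes. At resolution 1.0 there were 11 clusters, and the largest held 55.0% of 3d off and 42.7% of 5d off cells. Among the ductal markers the keratins were abundant: Krt18 had 2283, 2375, 2243 and 1502 CPM and Krt8 761, 1074, 1313 and 685 CPM. Others of that list were low, with Sox9 at 6.02, Cldn4 at 1.55, Epcam at 1.20 and Cftr at 0.562 CPM in the on library. UMIs summed over the ductal markers, mostly keratins, were 152962, 149053, 165815 and 89414. The 6 measured ductal markers had a median of -0.74 relative to all genes in on-off-on against 5d off. This lay below their random lists (percentile 1.5), while the other comparisons lay within theirs. By total UMIs 2 were lower and none higher, and with the shift of all genes taken off 1 was higher and none lower. Macrophage markers summed to 210, 208, 184 and 139 UMIs, mostly Cd68, with none for Adgre1 or C1qa, although Cd53 and Mrc1 were among the genes that differed most. Sums were 94, 96, 109 and 154 UMIs for acinar markers, 5, 2, 6 and 1 for endocrine, 23, 63, 64 and 47 for fibroblast, 1, 5, 18 and 7 for lymphocyte, and 26, 22, 40 and 90 for neutrophil markers. Endothelial markers gave 791, 727, 623 and 737 UMIs, nearly all from Egfl7, and red cell markers 78, 4, 6 and 8. Pericyte and smooth muscle markers gave 7, 137, 509 and 60 UMIs, mostly Mcam.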

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

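No test was run in this part, since each condition has 1 library, and the differences between the days were not tested. For 2 results, withdrawal gave opposite directions at 3 and 5 days. The S phase list lay at -0.29 relative to all genes in 3d off against on (percentile 0.5 of its random lists) and at 0.46 in 5d off against on (percentile 99.7). This holds only after the shift of all genes is taken off: the raw medians planned at first were 0.05 and 0.96. With cells called G1 alone both signs turned, to 0.08 and -0.12. Those calls come from the S and G2/M lists themselves, so this choice moves the S phase median by construction and decides nothing here. Txnip, a gene that restrains glucose uptake, had a log2 ratio of 1.42 in 3d off against on and of -1.09 in 5d off against on, with levels of 9.20, 24.7 and 4.31 CPM in the on, 3d off and 5d off libraries.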

How the results depend on the processing

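2 alternatives were chosen after the data were seen: leaving out the cells of cluster 5 and leaving out barcodes under 1% mitochondrial UMIs. In all, recomputing 367 results under the alternatives gave 2964 values. Of these values, 2403 were counted as unchanged, 552 as moved and 9 as changed in sign. Unchanged meant within the counting interval, or for a count within 1.5 times. For a list percentile it meant that the call held, and for an overlap of clusters that it passed a fixed share. For lists within their random lists in the main analysis a change of sign was not counted. The ERK output median in on-off-on against on was such a case, with values from -0.02 to 0.25. Removing doublets moved no value that answers a comparison. With 10 expression bins in place of 20, the housekeeping medians at 3d off and 5d off against on, that of mitochondrially encoded genes in on-off-on against on and that of fatty acid synthesis in on-off-on against 5d off fell within the random range. Unless a sentence says otherwise, the cause of a difference was not tested. Values named for a list are medians relative to all genes. Depth limits the low genes most: a floor of 3 counts is 0.080 CPM in the on library and 0.095 CPM at 3d off, and cells thinned to 16627 UMIs held a median of 1 Kras UMI at 3d off. No alternative planned went without being run.

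At 1.5-fold in place of 2-fold, the counts of higher and lower genes grow by construction: 2138 and 428 in 3d off against on, 3153 and 613 in 5d off against on, 1267 and 441 in 5d off against 3d off, 2475 and 682 in on-off-on against on, and 880 and 1728 in on-off-on against 5d off.

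Median-of-ratios scaling gave 380 higher and 345 lower genes in 3d off against on, 645 and 725 in 5d off against on, 183 higher in 5d off against 3d off, and 437 and 582 in on-off-on against on. This follows from its construction, which takes off the shift of all genes. Kras in on-off-on against on turned to -0.02. The return of genes higher at 3d off came to 74.5%. On that scale Kras was at 391 CPM in the on library, 104 at 5d off and 387 in on-off-on. The ERK output sum was at 2039, 1174, 1739 and 2232 in the on, 3d off, 5d off and on-off-on libraries.

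Totals without mitochondrially encoded and ribosomal protein genes are smaller by construction, so levels are higher: Kras had 601, 132, 175 and 660 CPM and the ERK output sum 3131, 2028, 2915 and 3808 CPM in the same order. Lower genes numbered 215 in 3d off against on. In 5d off against on the counts were 816 higher and 552 lower, in 5d off against 3d off 165 and 220, in on-off-on against on 650 and 423, and in on-off-on against 5d off 507 were higher. Of genes higher at 3d off, 61.3% returned.

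With each cell weighted alike, Kras had 329, 113 and 439 CPM in the on, 5d off and on-off-on libraries and the ERK output sum 1669, 1909 and 2336 CPM. Weighting cells alike, 3d off against on gave G2/M -1.11, respiratory chain 0.03, ribosomal proteins -0.66 and housekeeping 0.16. Medians so weighted in 5d off against on were ERK output -0.93, G2/M -0.53, glycolysis -0.69, cholesterol -1.36, mesenchymal 1.96, YAP/TAZ 0.90 and stress responses -1.27. MYC targets -0.66, ribosomal proteins -1.19 and housekeeping 0.32 were the values for 5d off against on. Weighting cells alike, 5d off against 3d off gave ERK output 0.25, G2/M 0.58, cholesterol -1.40, fatty acid synthesis -0.47, epithelial -0.35, interferon -0.42 and stress responses -0.40. Medians so weighted in 5d off against 3d off were MYC targets 0.30 and WNT -0.38. Immediate early genes -0.52, S phase 2.02, G2/M 0.98, mitochondrial genes 0.31, lysosome -0.40, epithelial -1.13, interferon -1.40 and MYC targets 0.51 were the values for on-off-on against on. Weighting cells alike, on-off-on against 5d off gave ERK output 1.15, S phase 1.36, G2/M 1.51, quiescence -0.39, lysosome -0.82, fatty acid synthesis 0.32 and fatty acid oxidation -0.77. Medians so weighted in on-off-on against 5d off were mesenchymal -1.43, interferon -1.50, YAP/TAZ -0.76, MYC targets 0.93 and ribosomal proteins 0.44.

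Every deposited barcode kept, 5d off against 3d off gave epithelial -0.31. Medians in on-off-on against on were mitochondrial genes 0.42. The stricter cell filter gave an ERK output sum of 1197 CPM at 3d off and 2032 CPM at 5d off, and 83.6% of 3d off cells at or above the 5th percentile of on cells. Under the stricter filter, 3d off against on gave ribosomal proteins -0.63. Strictly filtered medians in 5d off against on were ribosomal proteins -1.18 and housekeeping 0.45. ERK output 0.37, quiescence -0.25 and interferon -0.78 were the values for 5d off against 3d off. Under the stricter filter, on-off-on against on gave immediate early genes -0.52, mitochondrial genes 0.29 and ribosomal proteins -0.78. Strictly filtered medians in on-off-on against 5d off were ERK output 0.97 and ribosomal proteins 0.43.

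Cells called G1 alone leave out the cells with most S and G2/M UMIs, which bears on those lists. They numbered 462, 651, 608 and 81 in the on, 3d off, 5d off and on-off-on libraries, so on-off-on values rest on few cells. On this choice 597 genes were higher in on-off-on against on and 174 in on-off-on against 5d off. The return of genes higher at 3d off was 53.8%. With G1 cells alone, 3d off against on gave immediate early genes 0.43, S phase 0.08, G2/M -0.43, glycolysis -0.53, hexosamine -0.89, lysosome 0.39 and mesenchymal 1.5. G1 medians in 3d off against on were YAP/TAZ 0.76, hypoxia -0.81, ribosomal proteins -0.72 and housekeeping 0.16. ERK output -0.93, S phase -0.12, G2/M -0.53, glycolysis -0.76, hexosamine -0.87, cholesterol -1.37 and mesenchymal 2.20 were the values for 5d off against on. With G1 cells alone, 5d off against on gave YAP/TAZ 0.91, stress responses -1.17, hypoxia -0.88, MYC targets -0.69 and TGF-beta 0.96. G1 medians in 5d off against 3d off were S phase -0.18, G2/M -0.05, quiescence -0.46, interferon -0.48, stress responses -0.38, MYC targets 0.25, ribosomal proteins -0.61 and WNT -0.43. ERK output 0.25, immediate early genes -0.23, S phase 0.33, G2/M 0.26, hexosamine -0.42, mitochondrial genes 0.46 and lysosome -0.03 were the values for on-off-on against on. With G1 cells alone, on-off-on against on gave epithelial -0.56, mesenchymal 1.40, interferon -0.68, cytokines -0.02, hypoxia -1.0, MYC targets 0.11 and ribosomal proteins -0.53. G1 medians in on-off-on against 5d off were ERK output 1.14, S phase 0.56, G2/M 0.76, quiescence -0.45, respiratory chain -0.05, lysosome -0.55 and cholesterol 1.11. Epithelial -0.26, mesenchymal -1.19, interferon -0.45, MHC class I -0.46, cytokines -0.45, YAP/TAZ -0.81 and MYC targets 0.68 were the values for on-off-on against 5d off. With G1 cells alone, on-off-on against 5d off gave ribosomal proteins 0.82, TGF-beta -0.66 and NRF2 0.72.

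Filters on low counts change which members are measured, which moves medians by construction. A minimum of 5 CPM gave 212 lower genes in 5d off against 3d off. At 5 CPM, 3d off against on gave immediate early genes 0.37, G2/M -1.07, mesenchymal 0.93, YAP/TAZ 0.45, stress responses -0.62 and ribosomal proteins -0.67. Medians at 5 CPM in 5d off against on were hexosamine -0.72, lysosome 0.61, mesenchymal 1.77, YAP/TAZ 0.75, ribosomal proteins -1.22 and housekeeping 0.32. ERK output 0.20, interferon -0.42, ribosomal proteins -0.60 and WNT -0.32 were the values for 5d off against 3d off. At 5 CPM, on-off-on against on gave immediate early genes -0.42, hexosamine -0.39, mitochondrial genes 0.30, epithelial -0.89, mesenchymal 0.47, interferon -0.78 and cytokines -0.02. Medians at 5 CPM in on-off-on against on were stress responses -0.59, hypoxia -1.05 and MYC targets 0.49. ERK output 1.30, quiescence -0.48, lysosome -0.81, epithelial -0.42, mesenchymal -1.26, interferon -1.0 and MYC targets 0.94 were the values for on-off-on against 5d off.

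A minimum of 50 CPM gave 215 higher and 44 lower genes in 3d off against on, 515 and 74 in 5d off against on, 98 and 31 in 5d off against 3d off, 275 and 78 in on-off-on against on, and 76 and 285 in on-off-on against 5d off. At 50 CPM, 3d off against on gave ERK output -1.08, immediate early genes 1.01, S phase -0.56, G2/M -0.81, glycolysis -0.31, hexosamine -0.50 and lysosome 0.63. Medians at 50 CPM in 3d off against on were mesenchymal 1.56, MHC class I 0.51, cytokines 0.40, YAP/TAZ 0.91, receptor kinases 0.14, stress responses -0.66 and hypoxia -0.49. Ribosomal proteins -0.55, TGF-beta 0.76 and housekeeping 0.27 were the values for 3d off against on. At 50 CPM, 5d off against on gave ERK output -0.36, G2/M -0.22, glycolysis -0.48, hexosamine -0.66, lysosome 0.86, cholesterol -1.05 and mesenchymal 3.21. Medians at 50 CPM in 5d off against on were YAP/TAZ 1.03, heat shock -1.03, hypoxia -0.09 and TGF-beta 0.74. ERK output 0.58, immediate early genes -0.78, S phase 1.10, G2/M 0.55, quiescence -0.61, cholesterol -1.59 and epithelial -0.34 were the values for 5d off against 3d off. At 50 CPM, 5d off against 3d off gave mesenchymal 1.49, interferon -0.72, hypoxia 0.38, MYC targets 0.28, ribosomal proteins -0.71, WNT -0.22 and NRF2 0.17. Medians at 50 CPM in on-off-on against on were immediate early genes -0.36, S phase 2.21, G2/M 0.89, hexosamine -0.85, mitochondrial genes 0.22, epithelial -0.91 and mesenchymal 1.00. Stress responses -0.52, hypoxia -0.34, MYC targets 0.51 and ribosomal proteins -0.74 were the values for on-off-on against on. At 50 CPM, on-off-on against 5d off gave ERK output 0.49, S phase 1.63, G2/M 0.77, quiescence -0.45, lysosome -1.17, cholesterol 0.18 and fatty acid synthesis 0.31. Medians at 50 CPM in on-off-on against 5d off were fatty acid oxidation -0.90, epithelial -0.54, mesenchymal -2.47, MHC class I -1.12, cytokines -1.31, YAP/TAZ -1.47 and MYC targets 0.95. Ribosomal proteins 0.47 and NRF2 0.34 were the values for on-off-on against 5d off.

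No filter on low counts gave 3055 higher and 688 lower genes in 3d off against on, 4399 and 1088 in 5d off against on, 1396 and 1001 in 5d off against 3d off, 3203 and 1014 in on-off-on against on, and 1377 and 2652 in on-off-on against 5d off. Without that filter, 3d off against on gave ERK output -1.56, immediate early genes 0.37, hexosamine -0.72, mesenchymal 0.54, MHC class I 0.26, YAP/TAZ 0.46 and receptor kinases 0.82. Unfiltered medians in 3d off against on were stress responses -0.61 and ribosomal proteins -0.66. ERK output -1.21, hexosamine -0.69, mesenchymal 1.89, YAP/TAZ 0.76 and housekeeping 0.33 were the values for 5d off against on. Without that filter, 5d off against 3d off gave S phase 0.96, G2/M 0.90, quiescence -0.28, interferon -0.23, stress responses -0.21, hypoxia -0.41 and MYC targets 0.52. Unfiltered medians in 5d off against 3d off were ribosomal proteins -0.53 and WNT -0.02. G2/M 0.89, hexosamine -0.36, lysosome -0.27, epithelial -0.49, interferon -0.42, cytokines 0.05 and stress responses -0.57 were the values for on-off-on against on. Without that filter, on-off-on against on gave hypoxia -1.04, MYC targets 0.50 and ribosomal proteins -0.77. Unfiltered medians in on-off-on against 5d off were ERK output 1.28, quiescence -0.42, fatty acid synthesis 0.26, epithelial -0.42, mesenchymal -1.08, interferon -1.0, MHC class I -0.44 and ribosomal proteins 0.42.

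Of the alternatives added later, leaving out cluster 5 put 85.1% of on-off-on cells in S or G2/M. Without cluster 5, on-off-on against on gave mitochondrial genes 0.36, epithelial -0.97, interferon -0.99 and ribosomal proteins -0.77. Medians without cluster 5 in on-off-on against 5d off were ERK output 0.98, G2/M 1.11, respiratory chain -0.23, interferon -1.06, ribosomal proteins 0.50 and TGF-beta -0.85. Without low-mitochondrial barcodes, 5d off against on gave glycolysis -0.70, stress responses -1.15 and ribosomal proteins -1.23. Medians in 5d off against 3d off were quiescence -0.23 and ribosomal proteins -0.65. Mitochondrial genes 0.34 and epithelial -1.09 were the values for on-off-on against on. Without low-mitochondrial barcodes, on-off-on against 5d off gave ribosomal proteins 0.47.

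Selecting on 5d off and on and reading on-off-on against 3d off gave a return of 19.6% of higher and 25.3% of lower genes, with no share over all genes beside it. Of 3d off cells, 83.5% lay at or above the 5th percentile of on cells after thinning to the lowest 25th percentile and 84.1% with no thinning, which gave 93.6% at 5d off. At Leiden resolution 0.3 the largest cluster held 73.9% of 5d off and 90.6% of on-off-on cells. Resolution 1.0 gave 11 clusters, and the largest held 65.9%, 55.0%, 42.7% and 55.7% of on, 3d off, 5d off and on-off-on cells; more clusters at a higher resolution follow from its construction. With S phase and G2/M phase genes used, the largest held 70.5% of on and 79.2% of 3d off cells, and with 1000 variable genes 81.0% of 3d off and 57.6% of on-off-on cells.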

Other observations

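Of the tests in this part, those of cluster 5 on the S phase list and of shallow cells in other libraries were written down before their results were seen. The others, and the comparison of clusters 6 and 3, were chosen after the result was seen.

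The 5d off library was not uniform. Cluster 6, with 165 of its 878 cells, was called S or G2/M in 87.2% of cells, against 8.07% in cluster 3, with 621 cells, where the genes of those lists were left out of the clustering. Other cell cycle genes, such as Plk1 and Prc1, were open to use in it, so the difference is not independent of the clustering. Ube2c was at 380 against 10.3 CPM, Birc5 at 224 against 8.32, Top2a at 204 against 8.36 and Mki67 at 59.6 against 2.29. The S and G2/M medians were 1.78 and 3.27 relative to all genes, and MYC targets lay at 0.46. ERK output (0.35, with 3 of 17 members higher) and mesenchymal genes (0.28, with 4 of 14 higher) were also above their random lists, and stress response genes (0.24) lay at percentile 97.6. Members of these and the other lists, save S, G2/M, mitochondrially encoded and ribosomal protein genes, were open to use in the clustering. Their medians thus describe the clusters only.

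The epithelial list lay at -0.13 in cluster 6 against cluster 3 (percentile 11.4, 2 of 12 lower), within its random lists. Lowest by ratio were the trefoil factor Tff2, at 0.274 against 16.8 CPM (3 UMIs in cluster 6; log2 ratio -5.71, -8.22 to -4.37), Lgals4 at 5.03 against 51.0, the calcium binder S100g at 3.48 against 30.9, the water channel Aqp1 at 1.74 against 15.3 and Gsta1 at 0.732 against 5.62 CPM. Acta2 was at 1098 against 262, Cnn1 at 383 against 122 and Tagln at 103 against 37.9 CPM. These genes were open to use in the clustering, so they describe the clusters only. Medians were low for mitochondrially encoded genes (-0.67), lysosome (-0.44), receptor kinases (-0.37), stem markers (-0.37), fatty acid oxidation (-0.29), immediate early genes (-0.24) and MHC class I (-0.24). The median cell had 59521 UMIs in cluster 6 and 32112 in cluster 3, and 3 of the cluster 6 cells were called doublets.

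In the on-off-on library, 241 cells formed cluster 5, in which 63 genes were 2-fold or more above cluster 4 (median log2 ratio 1.56 with no shift taken off), led by Slc39a1 (345 against 28.9 CPM), Abhd2, Notch2 and Actb (19614 against 2633 CPM). Their lower depth (a median of 22938 against 49758 UMIs) cannot be told apart. Equally shallow cells of the on, 3d off and 5d off libraries (26, 99 and 169 cells) were set against deeper ones. There the same genes had medians of 0.92, 0.40 and 0.24 relative to all genes (2 standard errors are 0.13, 0.09 and 0.09). Standard errors here and below come from resampling the 63 genes and leave out the spread between cells. These medians lie above 0. At 3d off and 5d off they lie below the bound of 0.5 set beforehand by more than 2 standard errors. The highest, from 26 shallow cells of the on library, does not, which leaves the question undecided. None reached 2-fold, the size set beforehand for depth as the cause. A stronger response to doxycycline cannot be told apart either. The same genes had a median of 0.28 (2 standard errors are 0.20) in the other on-off-on cells against 5d off, above 0. They were chosen as lower in cluster 4, which makes up most of those cells, so this value is biased down and the test decides nothing. Between clusters 5 and 4, Kras (500 against 394 CPM) and Dusp6 (85.3 against 71.8) were higher, Fosl1 (52.7 against 69.1) and Etv4 (29.0 against 33.6) lower, and Etv5 was at 13 against 13.7 CPM. Transcripts with long runs of T may be over-counted in these cells: 88.9% of the 63 genes (78.4 to 95.4) hold a run of 15 T in their longest annotated transcript, against 8.23% of other genes and at most 28.6% in draws matched on length. Runs of A were found in 4.76%. How such a run would act was not tested, and levels of Actb, Spry2 and Insig1 in on-off-on (2856, 22.9 and 21.6 CPM without cluster 5) should be read with it.

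A small group of 64 barcodes, cluster 7, had very high Acta2 and a median of 0.0528% mitochondrial UMIs at 5d off and 0.238% in on-off-on; it gave 78.5% of the Acta2 UMIs of on-off-on and 26.2% of those at 5d off. Cells of another type are argued against, since Krt8 and Krt18 were at least 1.34 times their level in the rest of the library. The barcodes may be cell fragments without a nucleus: the nuclear RNAs Malat1, Neat1 and Kcnq1ot1 were at most 0.134 times their level in the rest. Doublets are argued against by the same RNAs, since merged cells keep their nuclei and the highest upper bound of these ratios was 0.152. Scrublet called none of these barcodes, and their median UMIs were 0.558 (0.416 to 0.746) and 0.646 (0.311 to 1.11) times those of the rest at 5d off and in on-off-on. Low RNAs were not the nuclear ones alone: Serpine1 and Timp3 were at 0.0338 and 0.0404 times the rest at 5d off. In on-off-on these barcodes held no Serpine1 UMI, and Timp3 was at 0.114 times the rest. No other biological explanation was tested.

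S phase and G2/M genes lay above the on library in on-off-on although both had doxycycline. Cluster 5 is argued against by a S phase median of 1.68 (1.59 to 1.80) without it. A gene dose above that of the on library cannot be told apart from other causes: the ERK output median was 0.02 (-0.03 to 0.08), but its members went both ways. Kras itself was 1.26-fold above the on library by total UMIs, with a log2 ratio of -0.02 under median-of-ratios scaling. The time since doxycycline came back, which the labels do not give, stays open as a biological difference and was not tested.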
